A study of Mus musculus with 6 samples.

How the data were processed

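MC38 mouse colorectal cancer cells were grown in serum-containing medium with 50 µM EPA free fatty acid for 24 h or as controls, with 3 samples per group, per the labels. Total RNA was amplified to biotin-labelled cRNA for Illumina arrays, per the labels' protocols. The exports of the series name GenomeStudio 1.7.0, quantile normalisation and MouseWG-6 v2 array content, per the file headers.

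The values analysed were the deposited series table of intensity, with 30828 target IDs for each of the 6 samples. The deposited intensity values are linear and above 0. Their sorted values differed between arrays by at most 0.465% (median 0.0125%), the mark of quantile normalisation. Array medians were 35.2 on all 6 arrays, so array-wide shifts of RNA amount cannot be seen. How the authors combined several probes of a target, and whether they corrected background or added a constant, is not given in the sources used here. The authors' deposited table of their own comparison gives a ratio per target, its log2 value, a raw p-value, and a p-value named as Benjamini-Hochberg adjusted, with the test not stated. In 4 cases the adjusted p is below the raw p beside it, and it never falls down the table, which runs by absolute log2 value and not by raw p. Neither fits an adjustment of the raw p beside it, so the deposited adjusted p was not used. The deposited ratio and log2 columns run in the direction EPA over control, as set against the series table. The deposited probe list was used only to count probes per target, and 21855 targets had 1 probe, 8946 had 2 or more and 27 had none listed. In other tables of the series, 102 columns of per-array values carry array numbers that match no sample label, and they were not used here.

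Targets were named through the RefSeq gene table of assembly GRCm38.p6, used for names only. A current symbol matched 16218 targets and 1 older synonym matched 5703, while 117 matched several symbols and 8790 none, and these last were left out. The IDs of 4 targets look like dates made by a spreadsheet.

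The plan fixed before the data were examined used background correction with neqc and detection p-values. These need columns that match no label, so log2 of the deposited intensities was tested instead, and the filter was set after the files were seen. Background was described by the mode of the intensities (28.06) and the spread of the values below it (SD 6.926). A target was kept if it exceeded 39.45, the mode plus a one-sided level of 0.05, on all 3 arrays of at least 1 group. This kept 11804 targets, of which 9811 had a name. The target with the highest mean log2 intensity over the 6 arrays stood for each symbol. Among 519 symbols with several targets above background, 10 had targets past the threshold in opposite directions. Adjusted p-values given for a second target of a gene come from a separate limma fit that kept several targets per gene. A fold against a group below background on all its arrays is given as "at least", with the dim group at the background limit. Other folds are ratios of geometric means. An uncorrected background makes them understate the change of dim genes. With the background level subtracted, the median absolute log2 fold change of the called genes was 0.50 instead of 0.39.

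Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 9272 genes, threshold 0.05). The 29 gene lists, including markers of other cell types, were fixed beforehand from general knowledge, and 26 had at least 5 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Of 13 lists past the threshold, 10 higher and 3 lower, 7 held with an estimated correlation, each named with its p beside it. Among those that did not hold, the estimate was above 0.01 for the PPAR (0.0454) and oxidative phosphorylation (0.0396) lists. It was below 0.01 for heat shock (-0.0374), mitosis (-0.0315), ribosomal proteins (-0.00964) and fibroblast markers (-0.096), so a higher correlation is not why these lost their calls. The unadjusted camera p of the heat shock list rose from 0.00174 to 0.0284 at its lower estimate. The estimate alone thus need not explain the PPAR and oxidative phosphorylation losses. The genes named are the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, the 4 members with the smallest p of each list that passed camera, and a panel of 24 genes. Of the panel, 17 were measured, with 7 higher, 4 lower and 6 not past the threshold, and some of these are not reported here by name. Pdk4, Cpt1a, Fasn, Srebf1, Abca1 and Ptgs2 did not pass the background filter, and no target was found for Hmgcs1. Further list members, and the other members singled out, were named after their values were seen.

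The fit was tested on simulated data for the 9272 genes of this comparison, with 200 genes changed. It recovered 90% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1. The simulated genes varied independently, and far fewer changed than were called here. The smallest simulated change also exceeded the median of the called genes (0.39), so these rates may not carry over to the data. Of the calls, 6.40% were unchanged genes, and with no change simulated 0 genes were called by limma, with 5.14% at an unadjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

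Other settings fixed beforehand were written for neqc values and run here on the deposited values. They were an offset of 16, median centring, cyclic loess, no filter and a stricter filter of 44.17 on all 6 arrays, the mean of a gene's targets, the replicate number as a block, array weights, an intensity trend with a robust prior, leaving out each array, all targets, an adjusted p under 0.01 and a plain equal-variance test. Added after the data were seen were an offset of 50, normexp background correction with offsets of 16 and 50, subtraction of the background level, and targets with 1 probe. Slide and position could not be tied to samples, so no batch was tested.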

Results

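MC38 is a mouse colorectal cancer cell line. Its gene expression was measured after 24 h in medium with 50 µM eicosapentaenoic acid (EPA), a long-chain omega-3 fatty acid, given as the free fatty acid, and in control cells. Each group had 3 samples of total RNA, and each sample was read on 1 Illumina mouse whole-genome bead array. The deposited table held 30828 target IDs per array as quantile-normalised intensities, with a median near 35.2 on every array. Of these targets, 11804 (38.3%) lay above background on all 3 arrays of at least 1 group, and they gave 9272 named genes for testing. The number of arrays limits the precision. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

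The comparison of EPA with control cells asked which genes differ with the fatty acid in these tumour cells. The sample annotation used here gives no time or vehicle for the control cells, so a difference in either cannot be told apart from EPA. Among genes above background in both groups, those for the chemokines Cxcl1, Ccl2 and Ccl7, which attract neutrophils and monocytes, and Angptl4, a secreted lipase inhibitor and fatty acid-responsive PPAR target, rose most. The lists of matrix and mesenchymal genes, endoplasmic reticulum chaperones, lysosome and autophagy genes, NRF2 antioxidant genes, and hypoxia and glycolysis genes also rose. Genes of the ATF4 stress response fell as a group, and the largest single falls included host genes of small nucleolar RNAs. In limma, 3155 of the 9272 genes (34.0%) passed an adjusted p of 0.05, with 1709 higher and 1446 lower with EPA. Most of these changes were small. The median absolute log2 fold change of the called genes was 0.39, and 69 genes changed at least 2-fold, 40 up and 29 down. The 3 EPA arrays lay entirely above or below the 3 control arrays for 4413 genes (47.6%), where chance alone gives 10%. Correlations of log2 intensity across genes were 0.995 to 0.997 within groups and 0.983 to 0.986 between groups, and the first principal component, with 69.0% of the variance, separated the groups.

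**Figure D1:**
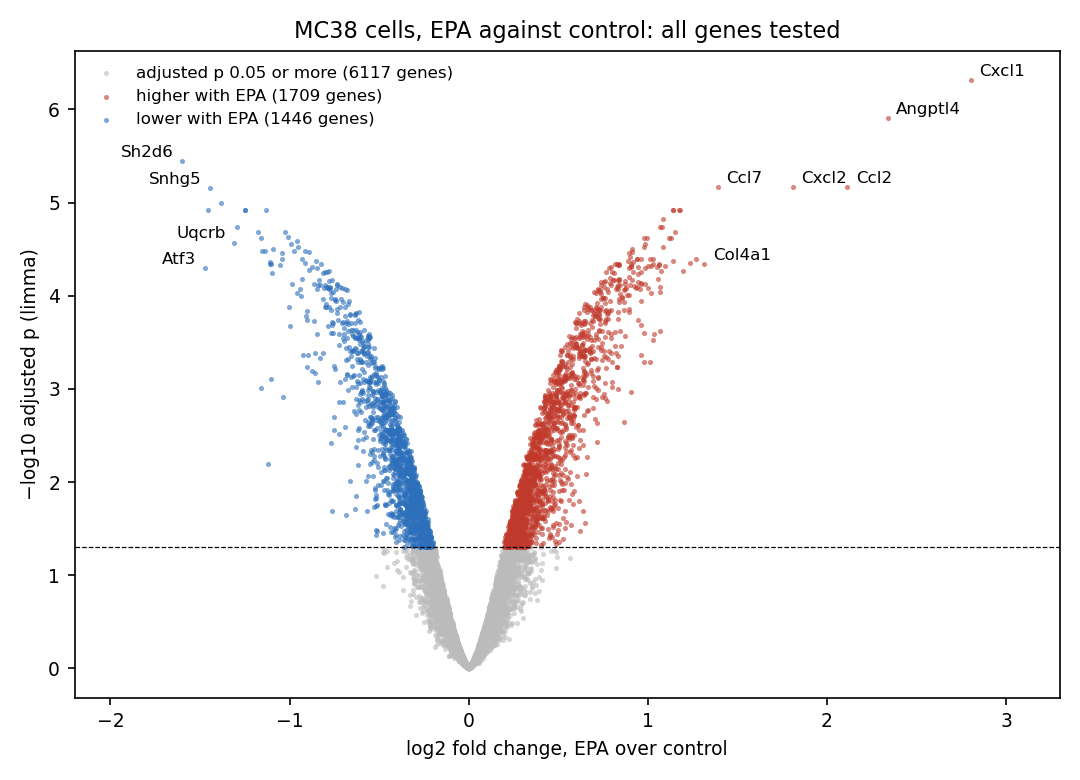
Log2 fold change, EPA over control, against −log10 of limma's adjusted p for the 9272 genes tested (1 point per gene; 3 arrays per group; dashed line at an adjusted p of 0.05). Of these, 1709 genes lay above the line on the right and 1446 on the left, and Cxcl1 and Angptl4 stood furthest out.

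Cxcl1 intensity was 794 ± 63.4 (SD, n = 3) in control cells and 5552 ± 499 with EPA, a 6.99-fold rise (log2 2.80, SE 0.0913, limma adjusted p = 4.84e-07). Ccl2 rose 4.33-fold, from 161 ± 16.4 to 701 ± 92.9 (limma adjusted p = 6.85e-06), and Ccl7 rose 2.62-fold, from 362 ± 10.8 to 951 ± 32.8 (limma adjusted p = 6.85e-06). Cxcl2 was below background in all control arrays (24.8 ± 2.26) and reached 87.0 ± 7.18 with EPA, at least 2.20-fold higher when the control is set at the background limit. Of the 19 measured genes on the fixed list of NF-kB and inflammatory genes, 11 rose, 0 fell and 8 did not pass, with 11 higher and 1 lower when adjusted over the list alone. Nfkbia, the NF-kB inhibitor that NF-kB itself induces, rose 1.76-fold, and the adhesion molecule Vcam1 rose 2.10-fold. The cytokine Il6 had a log2 fold change of -0.33 and did not pass the test, and the NF-kB subunits Rela and Nfkb1 had log2 fold changes of -0.07 and -0.03. The list stood above the other genes with a limma camera adjusted p of 2.72e-05 (adjusted p = 0.0358 with an estimated correlation). Of the 24 immune cell markers fixed beforehand, 3 were above background (Cd14, Cd68 and Lyz1), and none of these passed the test.

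Matrix and mesenchymal genes made the strongest list, with a limma camera adjusted p of 1.45e-10 (adjusted p = 0.0358 with an estimated correlation). Of 32 measured members, 25 rose, 2 fell and 5 did not pass, with the same counts when adjusted over the list alone, and the median log2 fold change was 0.71. The basement membrane collagen gene Col4a1 rose 2.49-fold, from 409 ± 11.2 to 1027 ± 158. Lox, which crosslinks collagen, rose 2.41-fold from 1181 ± 122 to 2846 ± 273, and the matrix protein gene Tgfbi rose 2.35-fold from 430 ± 53.2 to 1007 ± 66.7. The matrix protease gene Mmp2 rose 2.22-fold, from 1678 ± 60.4 to 3736 ± 251 (limma adjusted p = 2.06e-05), and Col6a1, Tnc and Sparc rose 2.11-fold, 1.88-fold and 1.86-fold. The members that fell were the transcription factor Snai2 (log2 -0.69) and the matricellular gene Ccn1 (log2 -0.39). Snai1 rose 1.44-fold and Zeb1 1.29-fold, while Twist1 and Acta2 had log2 fold changes of 0.04 and -0.02. Markers of fibroblasts and endothelium moved in the same direction. Of 19 fixed, 7 were measured, and 6 of these rose, among them Dcn (2.10-fold), Pdgfra (1.78-fold) and Cav1 (1.72-fold), and S100a4 fell (log2 -0.47). That list had a limma camera adjusted p of 0.00292 (adjusted p = 0.0737 with an estimated correlation), the same counts held when adjusted over the list alone, and all 7 genes lay above background on the control arrays too. The genes Mrgprf (log2 1.18, SE 0.0706) and Pmp22 (log2 1.18, SE 0.0693), on none of the fixed lists, were also among the 12 largest rises.

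**Figure D2:**
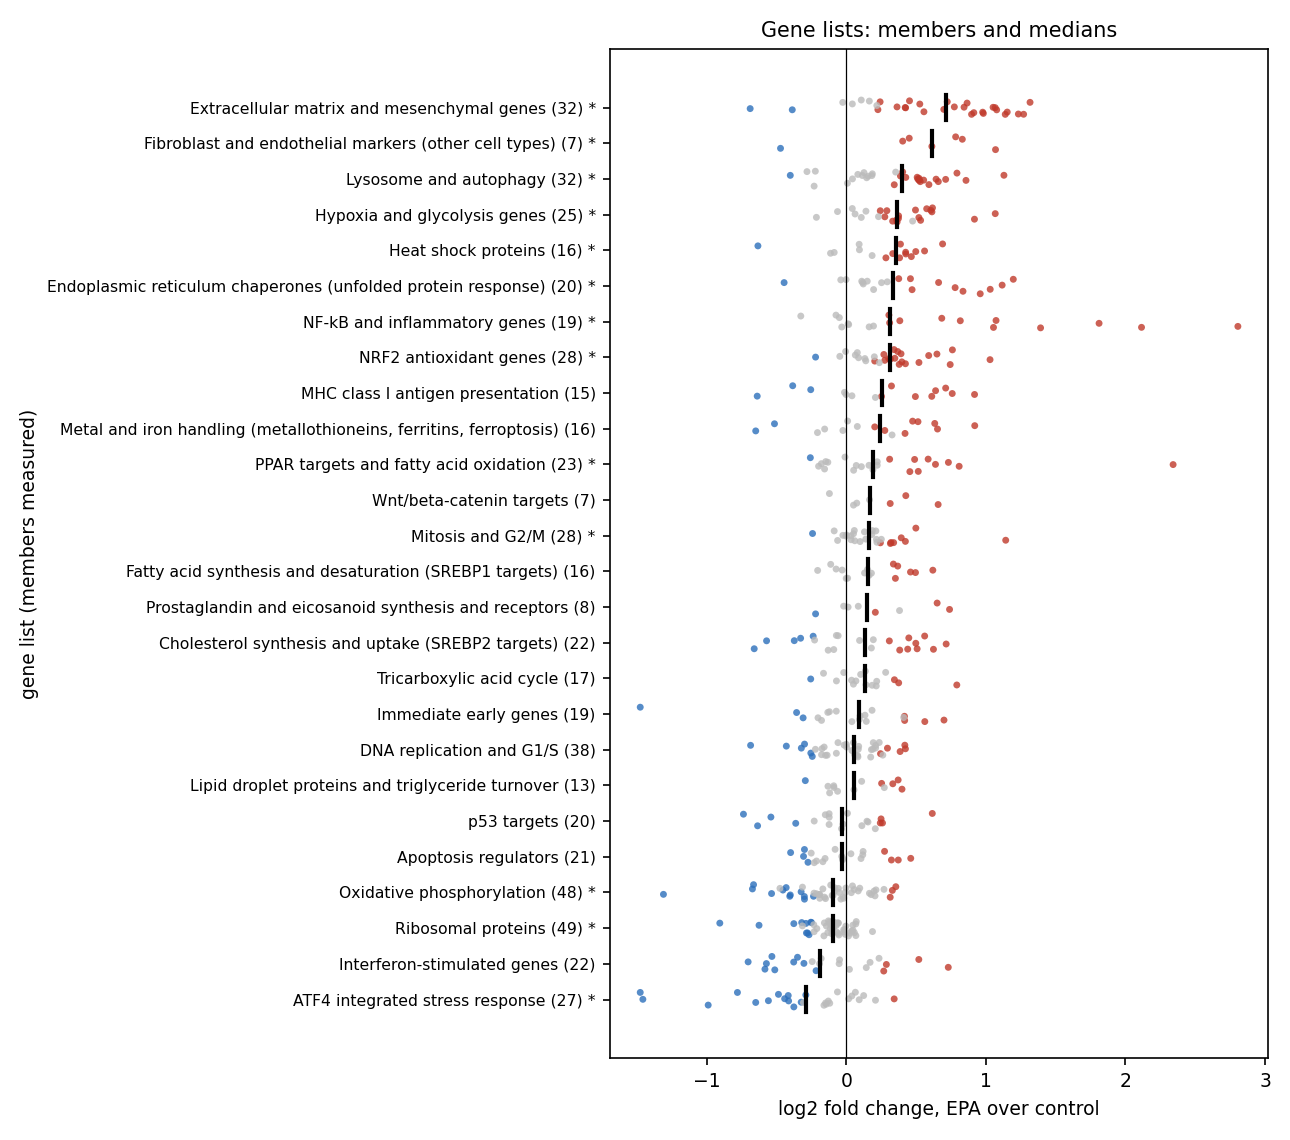
Log2 fold changes, EPA over control, of the measured members of 26 gene lists (1 point per gene; red, higher; blue, lower; grey, not past limma's adjusted p of 0.05; black bar, list median; asterisk, limma camera adjusted p under 0.05; number of members in brackets). The matrix list had the highest median, 0.71, and the ATF4 list the lowest, -0.29.

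Genes for protein folding in the endoplasmic reticulum rose. Of 20 measured, 10 rose, 1 fell (Sec61b, a subunit of the translocation channel, log2 -0.44) and 9 did not pass, with the same counts when adjusted over the list alone (limma camera adjusted p = 7.41e-05; adjusted p = 0.0358 with an estimated correlation). The calcium-binding chaperone gene Calr rose 2.29-fold, from 267 ± 17.4 to 615 ± 85.6, Creld2 rose 2.17-fold, and the disulphide isomerases Pdia4 and Pdia3 rose 1.94-fold and 1.79-fold. Hspa5, which encodes the main chaperone of that compartment, had a log2 fold change of 0.29 and did not pass. Its target read near background, at 42.3 ± 7.89 in control cells and 51.6 ± 6.50 with EPA. Only 2 of the control arrays were above background for it, so whether Hspa5 rose with the others cannot be told. Pdia6 did not pass on the target used (log2 0.11), but a second target of like intensity rose (log2 0.88, SE 0.11, limma adjusted p = 0.000338), so its change is not settled. Of 16 heat shock genes, 10 rose, 1 fell and 5 did not pass, with the same counts when adjusted over the list alone (limma camera adjusted p = 0.00453; adjusted p = 0.0737 with an estimated correlation). Hspb1 rose 1.61-fold, Hsph1 1.48-fold, Hsp90ab1 1.38-fold and Hspa8 1.34-fold, whereas Hspe1, a mitochondrial co-chaperone gene, fell (log2 -0.63). Lysosomal and autophagy genes rose in 18 of 32 cases, with 1 lower and 13 not past, or 18 higher and 4 lower when adjusted over the list alone (limma camera adjusted p = 2.44e-05; adjusted p = 0.0358 with an estimated correlation). Psap, the precursor of the saposins, rose 2.19-fold from 3299 ± 207 to 7213 ± 346, the protease genes Ctsb and Ctsa rose 1.81-fold and 1.56-fold, and Atp6ap1, an accessory subunit of the proton pump, rose 1.64-fold. The member that fell was the autophagy gene Atg12 (log2 -0.40).

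Genes of lipid metabolism moved unevenly. Angptl4 rose 5.07-fold, from 58.9 ± 5.41 to 298 ± 21.4 (log2 2.34, SE 0.0902, limma adjusted p = 1.23e-06). With the background level subtracted, an alternative chosen after the data were seen, its rise was 8.82-fold. Over all other settings its log2 fold change ran from 1.68 to 3.14. Of 23 measured PPAR targets and fatty acid oxidation genes, 9 rose, 1 fell (Acot2, log2 -0.26) and 13 did not pass, with the same counts when adjusted over the list alone (limma camera adjusted p = 0.00856; adjusted p = 0.185 with an estimated correlation). The oxidation enzyme genes Acaa2 and Acadl rose 1.75-fold and 1.66-fold, and the acyl-CoA thioesterase gene Acot1 rose 1.56-fold. Plin2, which coats lipid droplets, rose 1.32-fold. The lipid droplet list as a whole had 4 of 13 members higher and 1 lower, the same when adjusted over the list alone (limma camera adjusted p = 0.515). In cholesterol synthesis and uptake, 9 of 22 genes rose and 5 fell, or 9 and 6 when adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.358). Sqle, the squalene epoxidase gene, rose 1.42-fold, from 689 ± 12.7 to 980 ± 39.4 (log2 0.51, SE 0.0697, limma adjusted p = 0.000552). For fatty acid synthesis and desaturation, 6 of 16 rose and 0 fell, with the same counts when adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.0573; adjusted p = 0.241 with an estimated correlation). It passed under 7 alternatives, of which 2 were chosen after the data were seen and 1, fry, does not compare a list with other genes. The elongase genes Elovl5 and Elovl1 rose 1.54-fold and 1.41-fold. The fixed panel genes Scd1, Scd2, Fads2 and Insig1 had log2 fold changes of 0.16, -0.03, 0.18 and -0.07 and did not pass. Fads1 had 0.13 for the bright target used, which did not pass, and -0.72 (SE 0.147, limma adjusted p = 0.00484) for a second, dimmer target, which did, so its direction is not settled. Of 12 LXR targets, 2 were measured, and Lpcat3 rose 1.24-fold.

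Of 28 measured NRF2 antioxidant genes, 18 rose, 1 fell (Cbr1, log2 -0.22) and 9 did not pass, or 19 higher and 1 lower when adjusted over the list alone (limma camera adjusted p = 1.92e-05; adjusted p = 0.0358 with an estimated correlation). The epoxide hydrolase gene Ephx1 rose 2.04-fold, from 88.5 ± 4.18 to 181 ± 15.2, Gstm1 1.69-fold, the pentose phosphate enzyme gene Pgd 1.51-fold and the autophagy receptor gene Sqstm1 1.43-fold. Hmox1, which degrades haem, rose 1.68-fold (188 ± 23.4 to 316 ± 41.2; limma adjusted p = 0.00122). In hypoxia and glycolysis genes, 17 of 25 rose and 0 fell, or 19 and 0 when adjusted over the list alone (limma camera adjusted p = 5.6e-06; adjusted p = 0.0358 with an estimated correlation). The collagen prolyl hydroxylase genes P4ha1 and P4ha2 rose 2.10-fold and 1.89-fold, the glucose transporter gene Slc2a1 1.52-fold and enolase Eno1 1.53-fold. The 8 members that did not pass included Pdk1, Ndrg1, Ankrd37 and Vegfa. Vegfa, a classical hypoxia target, had a log2 fold change of -0.21, and it passed as a fall only without EPA replicate 3 (log2 -0.32). Of 16 metal and iron genes, 8 rose and 2 fell, or 9 and 3 when adjusted over the list alone (limma camera adjusted p = 0.096).

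The ATF4 integrated stress response fell. Of 27 measured genes, 13 fell, 1 rose and 13 did not pass, or 14 lower and 1 higher when adjusted over the list alone (median log2 -0.29, limma camera adjusted p = 5.7e-05; adjusted p = 0.0358 with an estimated correlation). Atf3, a stress-induced transcription factor, was 2.78-fold lower with EPA (225 ± 9.52 to 82.0 ± 16.6), and Ppp1r15a, which directs dephosphorylation of eIF2α, was 2.74-fold lower (1305 ± 118 to 475 ± 19.3; limma adjusted p = 1.19e-05). Ddit3, which encodes CHOP, was 1.98-fold lower and Trib3 1.72-fold lower. The amino acid supply genes did not all follow. The serine synthesis gene Phgdh rose 1.27-fold, and Asns and Psat1 had log2 fold changes of 0.04 and -0.06. Txnip, a thioredoxin-binding protein gene, fell (log2 -0.53, SE 0.113, limma adjusted p = 0.0058), and the call was lost without the filter on dim targets.

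Among the 12 largest falls, Sh2d6, an adaptor-protein gene, was 3.03-fold lower (128 ± 4.16 to 42.3 ± 1.89, limma adjusted p = 3.55e-06), or 7.07-fold lower with the background level subtracted. The log2 fold change of Sh2d6 ran from -2.82 to -0.95 over all other settings. The small nucleolar RNA host genes Snhg5, Snhg12, Snhg16 and Zfas1 were 2.72-fold, 2.45-fold, 2.37-fold and 2.26-fold lower. Mir17hg, the host of a microRNA cluster, was 2.24-fold lower, Angptl6 2.60-fold, the DNA helicase gene Recql4 2.38-fold and Nrbp2 2.24-fold. Uqcrb, a subunit of respiratory complex III, was 2.48-fold lower (470 ± 47.4 to 190 ± 14.6). Of 48 oxidative phosphorylation genes, 12 fell, 3 rose and 33 did not pass, or 15 lower and 4 higher when adjusted over the list alone (limma camera adjusted p = 0.0151; adjusted p = 0.208 with an estimated correlation). Atp5e, Ndufb9 and Atp5l were 1.59-fold, 1.45-fold and 1.37-fold lower, whereas Atp5b rose 1.28-fold. For ribosomal proteins 10 of 49 fell and 0 rose, the same when adjusted over the list alone (limma camera adjusted p = 0.00292; adjusted p = 0.0525 with an estimated correlation). Rps18, Rpl13a and Rps3 were 1.87-fold, 1.54-fold and 1.30-fold lower, and Rpl30 1.22-fold, a call lost without control replicate 2 and without the filter. In the tricarboxylic acid cycle, 3 of 17 rose and 1 fell, the same when adjusted over the list alone (limma camera adjusted p = 0.096).

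**Figure D3:**
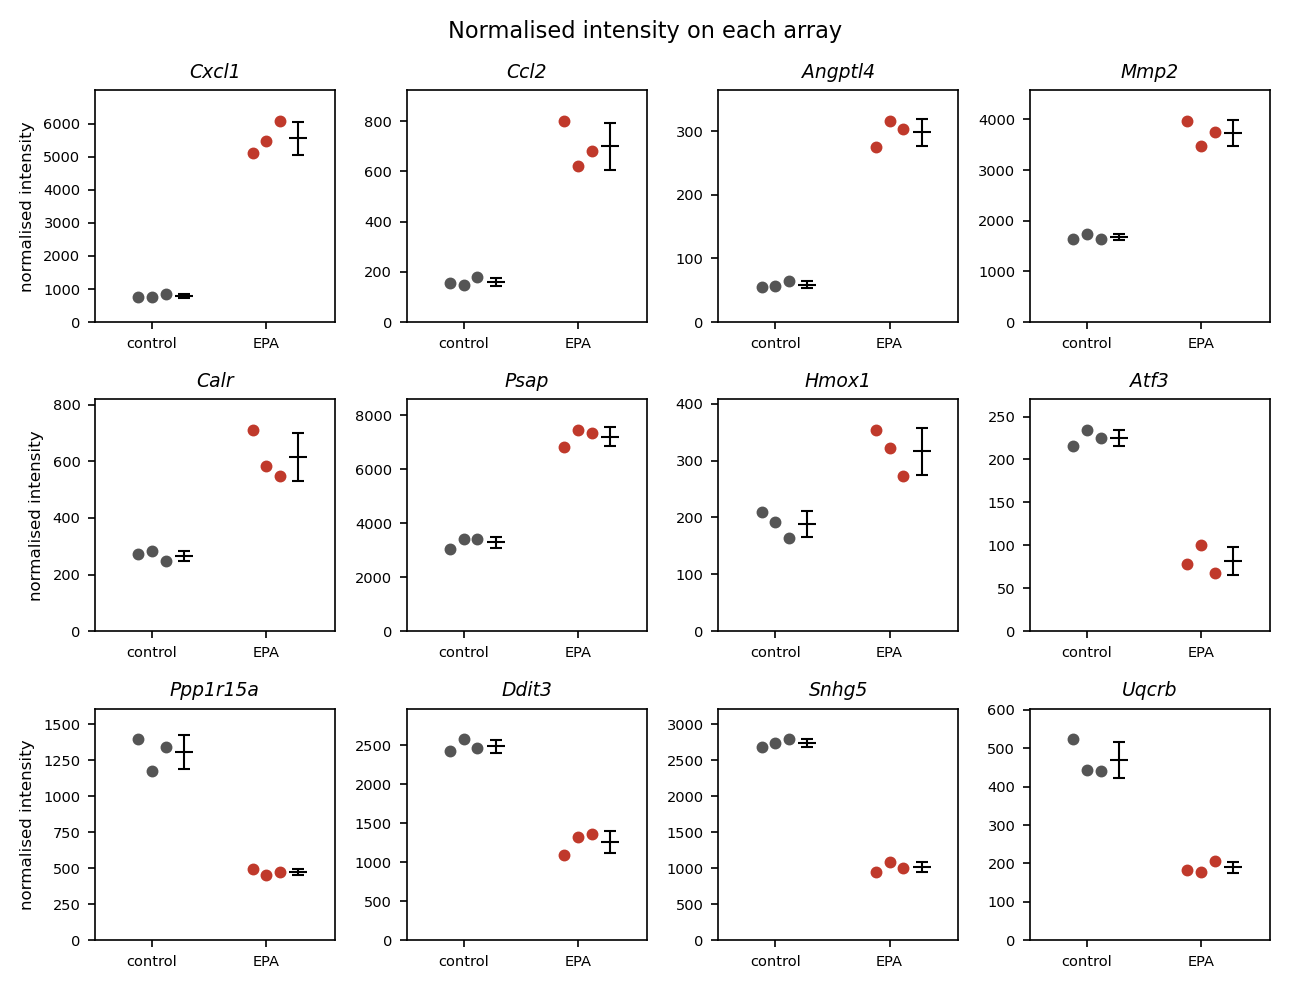
Normalised intensity (linear, deposited units; each panel starts at 0 with its own scale) of 12 genes on each of the 3 control and 3 EPA arrays, with the mean and SD at the right of each group. The 3 EPA arrays lay above the 3 control arrays for Cxcl1, Ccl2, Angptl4, Mmp2, Calr, Psap and Hmox1, and below them for Atf3, Ppp1r15a, Ddit3, Snhg5 and Uqcrb.

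Mitosis genes shifted by little. Of 28 mitosis genes, 8 rose, 1 fell (Mad2l1, log2 -0.24) and 19 did not pass, the same when adjusted over the list alone (limma camera adjusted p = 0.00995; adjusted p = 0.0782 with an estimated correlation). Kif23, a kinesin of cytokinesis, rose 2.21-fold on the target used, and its second target gave a log2 fold change of 0.29, so the size of its rise is uncertain. Anln rose 1.41-fold, Kif4 1.34-fold and Cdc20 1.25-fold, the last not without the filter. Cdk1 and Ccnb1 had log2 fold changes of 0.00 and 0.03. Of 38 DNA replication genes, 5 rose and 6 fell, the same when adjusted over the list alone (limma camera adjusted p = 0.864). Ccnd1, cyclin D1, rose 1.24-fold and Cdkn1a, the cyclin-dependent kinase inhibitor p21, 1.19-fold. Neither call held without the filter, and the Cdkn1a call was also lost without control replicate 2, control replicate 3 or EPA replicate 3. Of 20 p53 targets 4 rose and 4 fell (limma camera adjusted p = 0.515), and of 21 apoptosis regulators 4 rose and 4 fell (limma camera adjusted p = 0.414), with the same counts when adjusted over each list alone.

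Of 15 genes of class I antigen presentation, 8 rose and 3 fell, or 9 and 3 when adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.0508; adjusted p = 0.22 with an estimated correlation). It passed under 13 alternatives, of which 3 were chosen after the data were seen and 1, fry, does not compare a list with other genes. H2-D1 rose 1.89-fold, Tapbp 1.69-fold and B2m 1.41-fold, whereas Nlrc5, a transcriptional activator of these genes, fell (log2 -0.64) and Cd274, which encodes PD-L1, fell (log2 -0.25). Interferon-stimulated genes went both ways, with 4 of 22 higher and 9 lower, or 4 and 10 when adjusted over the list alone (limma camera adjusted p = 0.106). Irf9 and Stat2 fell (log2 -0.58 and -0.51) and Gbp2 rose 1.66-fold. The eicosanoid list had 3 of 8 genes higher and 1 lower, the same when adjusted over the list alone (limma camera adjusted p = 0.175), with Ptges, a prostaglandin E synthase gene, 1.67-fold higher. Ptgs2 was not above background. Of 7 Wnt targets 3 rose and 0 fell (limma camera adjusted p = 0.106), and of 19 immediate early genes 4 rose and 3 fell (limma camera adjusted p = 0.864), the same when adjusted over each list alone. Of 29 epithelial and intestinal genes, 4 were measured. For Ctnnb1, β-catenin, the brighter target had a log2 fold change of 0.32 (limma adjusted p = 0.0081) and a second target -0.48 (limma adjusted p = 0.00902), so its direction is not settled.

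The authors' deposited table lists 4423 targets with a raw p up to 0.05, 2140 with a ratio above 1 and 2283 below 1. Of these targets, 3078 stood for a gene tested here. All 3078 had a fold change in the direction the authors' deposited table gives, and the log2 fold changes correlated across genes with r = 1, as both come from the same arrays. Of the 3155 genes called here, 2627 are in the authors' deposited table and 528 are not. The thresholds differ, an adjusted p under 0.05 in limma here against a raw p up to 0.05 there.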

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

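The count of 3155 genes moved by more than 1.5 times without the filter on dim targets (1313), at an adjusted p under 0.01 (1765), with a plain equal-variance test (2004) and with targets of 1 probe (1461; fewer genes tested, 4855), the last chosen after the data were seen. Without the filter, 19964 genes were tested and limma gave 4156 at an unadjusted p under 0.05, against 4117 of 9272 with it. The adjustment thus ran over many more genes with few more small p-values. The threshold of 0.01 is stricter by construction, and the cause was not tested for the plain equal-variance test. Of the 26 lists tested, 13 passed with camera, 7 with an estimated correlation and 24 with fry, which does not compare a list with other genes. Background was treated in 6 ways: as deposited, offsets of 16 and 50, normexp with offsets of 16 and 50, and the background level subtracted. Except for the offset of 16, these alternatives were chosen after the data were seen. The counts were then 3205, 3287 and 2733 genes for normexp with offset 16, normexp with offset 50 and subtraction. Leaving out 1 array gave 2378 to 2956 genes and 13 to 15 lists. The replicate block gave 2926 genes and changed no call of a named gene or list. Deviations of same-numbered arrays correlated at -0.0352, -0.188 and 0.110, so the numbers do not pair the samples, and control 2 correlated best with EPA 1. Of the named genes, Fads1 changed sign with the mean of its targets (-0.29, the average of 0.13 and -0.72) and Fads2 passed with array weights. Scd2 changed sign with array weights (0.044) and when 1 array was left out (-0.17 to 0.17), never past the threshold. In all, 1501 values of named genes kept direction and side of the threshold, 11 lost a call, 2 gained one and 4 changed sign. For lists 499 kept both, 6 lost a call and 31 gained one. In the other 10, all of lists that did not pass, the median or camera's direction changed sign. Medians without the filter were -0.051 for lipid droplets, -0.0065 for cholesterol synthesis and 0.036 for immediate early genes, and with array weights -0.0065 for lipid droplets and 0.020 for apoptosis. Leaving out 1 array gave medians of -0.092 to 0.10 for lipid droplets, 0.024 to 0.080 for DNA replication, -0.10 to 0.0036 for apoptosis and -0.011 to 0.13 for immediate early genes. The log2 fold changes correlated with those of the authors' deposited table at 0.997 and 0.984 with offsets of 16 and 50. Median centring moved no count, since the arrays already share their median. The planned neqc settings and detection p filters were not run, as their columns match no label. Signal over background limits dim genes: the median intensity of 35.2 lies below the limit of 39.45.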

Other observations

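The list of small nucleolar RNA host genes and the families defined by name were chosen after the data were seen, as were the tests on immune markers, on fibroblast markers and on subtraction of the background level. Gene families defined by name, with at least 20 measured members, gave 8 of 40 past a limma camera adjusted p of 0.05, 2 higher and 6 lower, and none with an estimated correlation (adjusted p = 0.0914 at the lowest). Mitochondrial ribosomal proteins, which build the ribosome inside mitochondria, led. Of 70 measured, 33 fell and 0 rose, with a median log2 fold change of -0.22 (limma camera adjusted p = 7.42e-09; adjusted p = 0.0994 with an estimated correlation). Mrpl53 was 1.67-fold lower with EPA (4205 ± 107 to 2522 ± 67.5, SD, n = 3) and Mrpl20 1.62-fold lower. Of 178 zinc finger genes named Zfp, many of them transcription factors, 43 fell and 2 rose (median log2 -0.12, limma camera adjusted p = 0.000239; adjusted p = 0.0914 with an estimated correlation). Of 27 genes whose names begin with Cd and a digit, 14 rose and 2 fell (median log2 0.45, limma camera adjusted p = 0.00239; adjusted p = 0.0994 with an estimated correlation). The match is by name only, and it takes in Cd2bp2 (log2 -0.40), which is not itself a Cd antigen. The tetraspanin genes Cd81, Cd82 and Cd9 rose 1.91-fold, 1.53-fold and 1.53-fold. None of these median directions changed with cyclic loess.

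The host genes of small nucleolar RNAs carry these RNAs in their introns, and many spliced host transcripts are turned over during translation. Of 8 measured, 7 fell and 0 rose, with a median log2 fold change of -1.09 (camera p = 8.07e-09; p = 0.00395 with an estimated correlation), but they were grouped after 4 of them were seen among the largest falls. Snhg17 and Dancr fell by 1.01 and 0.83 on the log2 scale, and Snhg18 had -0.15. A candidate explanation is stronger nonsense-mediated decay. Factors of that pathway, which it represses, had a median of -0.141 over 6 measured genes, with 1 fall (Smg6), a value between the bounds set before it was seen, so the test leaves this open. Lower transcription of the hosts was not tested.

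The chemokine rise may be a response of the MC38 cells or may come from the measurement or from other cells. Additive background could hardly set its size for Cxcl1, Ccl2 and Ccl7, whose control means were 794, 161 and 362. The background mode was 28.06, so a test on these genes had little chance of another outcome. The median ratio of their folds after to before correction was 0.989 with normexp, the test set before its result was seen. It was 1.05 with the background level subtracted, and all 3 genes kept their calls. Cxcl2, below background in control cells, was left out of that test. Its fold was 3.51 as deposited and 8.47 with the background level subtracted, so the size of its rise depends on background. RNA of immune cells stays open. The 23 immune marker targets had a median log2 change of -0.0156, but 3 lay above background on all EPA arrays against 2 on all control arrays, which missed the bound set for excluding it. The marker behind that difference was Lyz1, near background at 46.8 in control cells and 49.3 with EPA. Ptprc, Tyrobp, Itgam and Cd74 were below background on all arrays. A second criterion, set after that result, was met: the largest rise among the markers was 5.58 intensity units, against 4758 for Cxcl1, and the brightest, Cd14, stood at 133 with EPA. Outside the fixed markers, Cd8b1 rose 1.78-fold (761 ± 70.2 to 1354 ± 96.5) and Cd300lb 1.36-fold. The fixed markers Cd8a, Cd3d and Cd3e were below background on all arrays.

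The matrix rise may likewise be a response of the cells. Against RNA of fibroblasts, Acta2 and S100a4 did not rise, and the intervals of Col1a1, Acta2 and S100a4 all lay below the matrix median of 0.71, which met the bound written for excluding it. That bound was wrong to include Col1a1, at 35.6 and 40.9 near background, and S100a4, whose high level in control cells would hide a small share, and the fixed markers had a median log2 change of 0.613, so fibroblast RNA stays open. None of those markers is on the matrix list, and all 7 measured are expressed in the control cells. A wider rise of genes for membrane and secreted proteins could also be part of it. The Slc family rose (limma camera adjusted p = 0.0471; adjusted p = 0.0994 with an estimated correlation) and the Tmem family did not pass (limma camera adjusted p = 0.491), so this was not settled.

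The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3155 genes in limma and the highest of the other splits 0, and 13 lists against at most 10. At an unadjusted p under 0.05 limma gave 4117 genes for the real split and 92 to 364 for the others. As many genes and as many lists came from 1 split, the real one. The other splits still hold part of the treatment difference.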
